A study of Mus musculus with 6 samples.

How the data were processed

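Naive CD4 T cells were isolated, per the labels' protocols, from the spleen and lymph nodes of wild-type C57/Bl6 mice. They were cultured on plates coated with antibodies to CD3 and CD28, with 20 ng/ml IL-4, 2 ng/ml TGFβ, an antibody that blocks interferon γ, and either no IL-1β or 10 ng/ml of it. There are 6 libraries in 6 groups: 2 culture conditions at each of 3 stages (1 h, day 3, and in vivo 1 week after injection). RNA of the 1 h libraries was depleted of rRNA and that of the other 4 was poly(A)-selected, per the labels. Sequencing was done on a MiSeq. The tissue the in vivo cells were taken from is not given in the sources used here.

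The submitters' processing notes name TopHat and the mouse genome build mm9. The version of TopHat and the tool that made the gene values are not given in the sources used here. The deposited files give FPKM per gene, made by the authors, with a lower and an upper bound per value, per the file headers; the level of these intervals is not given in the sources used here. Each file has 23700 entries. In every file 285 entries have a status other than OK and were left out of all comparisons. Entries that share a gene symbol were summed, with their bounds, which gave 23091 symbols, 190 of them from several entries. Between 19 and 319 entries per file have an FPKM above their own upper bound. The FPKM and the bounds were used as deposited. Library depth is not stated, and whole fragment numbers could not be recovered from the values. Only 10.1% to 11.5% of the recovered numbers lay within 0.05 of a whole number, against 10% for random values, so no limit for a value of 0 was computed. The median half-width of the intervals was 70.4% and 42.5% of the FPKM in the 1 h libraries without and with IL-1β, 23.7% and 25.3% at day 3, and 27.2% and 27.4% in vivo.

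The 7 comparisons were IL-1β against no IL-1β at each of the 3 stages, and day 3 against 1 h and in vivo against day 3 in each arm. The log2 ratio is that of FPKM with a pseudocount of 1. A gene was compared when it reached 5 FPKM in at least 1 of the 2 libraries, and counted by the rule given with the results. These comparisons by size carry no p-value. No fold is given against a value listed at 0.

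The rule for named genes, the gene lists, the tests and most alternatives were fixed before the data were examined. The named genes are the 10 largest and 10 smallest ratios among counted genes for the IL-1β comparisons, and 5 and 5 for the comparisons over time, without unnamed models. To these come a core list of 14 genes, up to 4 members per list with the largest absolute ratio, and every counted list member. Because many of the largest ratios came from genes listed at 0, the same number of genes above 0 in both libraries was added after seeing the data. Genes shared between stages, genes called by limma without the 1 h stage, and members given for level (Gapdh, Rn45s) were named after their values were seen. Results of some single genes of the lists are not reported here.

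There are 25 lists: core genes, NF-κB targets, interferon response, IL-1 receptor signalling, Th9, Th1, Th2, Th17, regulatory T cell, follicular helper, cytotoxic effector, inhibitory receptors, naive and memory, early activation, cell cycle, glycolysis, cholesterol biosynthesis, homing receptors and integrins, T cell identity, transcripts without a poly(A) tail, and markers of B cells, myeloid cells, erythroid cells and platelets, NK and CD8 cells, and stroma and epithelium. Some genes stand in several lists. A list's median is over members with at least 1 FPKM in 1 of the 2 libraries. It was set against 10000 random lists of the same size matched on mean expression in 20 bins. This describes the libraries and is not a test. Of 173 list and comparison pairs with a median, 79 lay outside the middle 95% of random lists, against 8.65 for random lists.

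The test across stages used limma 3.58.1 in R 4.3.3 on log2 of FPKM + 1, with stage as covariate, over genes with at least 5 FPKM in at least 1 library, with Benjamini-Hochberg adjustment at 0.05. Other values were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and drawn with matplotlib 3.10.9. Transcript lengths came from the GENCODE M21 annotation, matched by symbol, and the length trend was a lowess curve with a fraction of 0.3. Removing this curve also removes the overall shift between the 2 libraries. Coordinates are those of the files, on mm9, with starts counted from 1.

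The rules were tested on simulated data. With 100 genes raised 3-fold, the size rule counted 57 at 1 h, 89 at day 3 and 90 in vivo, and of 100 genes lowered 3-fold it counted 20, 68 and 53. It counted 0 of 941, 7 of 9931 and 17 of 10254 unchanged genes. The limma test called 31 of 100 genes with a log2 change of 2 and 71 of 100 with a change of 3, and 3 of 8746 unchanged genes, at the spread of these data.

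The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a minimum of 20 FPKM, a 3-fold minimum, equal median ratios or upper quartiles, no use of the intervals, and the highest entry of a symbol in place of the sum. For limma they were quantile normalization, no stage covariate, and leaving out each stage. Added after seeing the data were leaving out genes listed at 0, keeping genes with at least 5 FPKM in both day 3 libraries, and removing the length trend.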

Results

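RNA was sequenced from mouse CD4 T cells that had been driven toward the Th9 state, a helper T cell state named for its cytokine interleukin 9, in the presence or absence of interleukin 1β (IL-1β). The 6 libraries formed 6 groups of 1 library: Th9 cells and Th9 cells given IL-1β, each after 1 h of culture, after 3 days of culture, and in vivo. For the in vivo pair, cells carrying the CD45.2 allele had been cultured for 3 days, injected into mice carrying CD45.1 and recovered by sorting 1 week later. The values were the authors' FPKM (fragment values scaled to transcript length and to the mapped fragments of the library), with an interval for each gene in each library. Read depth was unknown, so its effect is visible only through these intervals. At day 3 and in vivo, between 7313 and 8154 genes reached 5 FPKM in a library. At 1 h, when rRNA-depleted instead of poly(A)-selected RNA was sequenced, 631 genes reached 5 FPKM without IL-1β and 765 with it. The 45S ribosomal RNA Rn45s made up 41.3% and 24.7% of the summed FPKM of these 1 h libraries. Transcripts without a poly(A) tail and small structured RNAs together made up 87.3% and 90.1%, against 0.17% to 0.67% in the poly(A)-selected libraries. A gene was counted as higher or lower when the ratio of (FPKM + 1) was at least 2-fold, the larger value was at least 5 FPKM, and the 2 intervals did not overlap. With 1 library per group, none of the differences within a stage has a replicate check. The words higher and lower below mean counted by this rule, unless a value is given without them.

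The comparison at 1 h asked how IL-1β changes RNA levels at the very start of differentiation. Nfkbiz, which encodes the nuclear NF-κB regulator IκBζ, was higher with IL-1β, at 10.6 FPKM (interval 7.13 to 14.0) against 2.46 (0 to 6.23), a log2 ratio of 1.74. The early activation marker Cd69 was higher at 51.2 against 23.3 FPKM (log2 ratio 1.10). The chemokine receptor Cxcr4 was higher at 14.9 against 2.57 FPKM (2.15), and Selplg, the ligand of P-selectin, at 13.5 against 3.49 FPKM (1.69). Arhgdib had the largest ratio among counted genes above 0 in both libraries, 31.8 against 4.51 FPKM (2.58). Ccl5, a chemokine gene, reached 14.4 FPKM with IL-1β and was listed at 0 without it. The immunoproteasome gene Psmb8 reached 11.1 FPKM and was also listed at 0 without IL-1β.

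Among the lists fixed in advance, NF-κB targets had 1 of 21 measured members higher (Nfkbiz) and a median log2 ratio of 0.60, above those of 97.4% of random lists matched on expression. Interferon response genes had 1 of 26 members higher (Psmb8) and a median of 0.67, above 97.7% of random lists. Of the 26 log2 ratios, 21 were above 0 and 5 below. Psmb9, of the same list, went the opposite way to Psmb8. It was listed at 0 with IL-1β and stood at 6.53 FPKM (0 to 13.3) without, and did not meet the rule. Irf1 (7.39 against 4.41 FPKM) did not meet the rule. Homing receptors and integrins had 2 of 16 members higher, Cxcr4 and Selplg, with a median of 0.60. The myeloid marker list had 1 of 8 higher, Tyrobp at 6.59 FPKM against a listed 0, with a median of 0.91, above 99.3% of random lists. Transcripts of other cell types stood in both 1 h libraries. With and without IL-1β, the erythroid marker Hba-a1 stood at 232 and 215 FPKM, the myeloid list member H2-Aa at 27.9 and 18.6 FPKM, and the B cell marker Cd79a at 5.45 and 9.10 FPKM. The values do not show which cells carried the RNA that differed at 1 h. Il9, Il10, Il21, Il4 and Il1r1 were listed at 0 in both libraries.

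In all, 74 of 933 compared genes were higher and 2 were lower at 1 h. The lower ones, Igbp1 and the unnamed model BC013529 (named after its value was seen), were listed at 0 with IL-1β. Of the 74 higher genes, 37 were listed at 0 without IL-1β, and Gapdh, an abundant glycolysis gene, was listed at 0 in the library with IL-1β and at 0.99 FPKM in the other. The library without IL-1β had wider intervals, with a median half-width of 70.4% of the FPKM against 42.5%. In simulated data for this comparison the rule counted 57 of 100 genes raised 3-fold and 20 of 100 lowered 3-fold. It thus finds higher genes more readily than lower ones. The median ratio of genes at 5 FPKM or more in both libraries was 0.21. Scaling this shift away left 47 genes higher and 3 lower. Nfkbiz (1.56, with overlapping intervals) and Cd69 (0.89) then no longer met the rule, so that 0 of 21 NF-κB targets did, while Cxcr4, Selplg, Arhgdib, Ccl5, Psmb8 and Tyrobp still met it. Equal upper quartiles gave 113 genes higher and 2 lower, with all of these genes higher.

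The comparison at day 3 asked how IL-1β changes the Th9 cells formed in culture. Il9 (mm9 chromosome 13, 56580638 to 56583607) had the largest ratio among higher genes above 0 in both libraries. It stood at 274 FPKM with IL-1β and 39.8 FPKM without, a 6.75-fold difference of (FPKM + 1) and a log2 ratio of 2.76. Its intervals were 149 to 227 and 16.5 to 48.4, so the higher value lies above its own interval. The metallothionein gene Mt1 was higher at 49.7 against 8.14 FPKM (2.47), and the stress-induced Nupr1 at 22.8 against 3.92 FPKM (2.27). Mcpt8, a mast cell and basophil protease gene, was higher at 7.59 against 0.868 FPKM (2.20). The chemokine gene Cxcl3 was higher at 5.97 against 0.681 FPKM (2.05).

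Rel, Nr4a3 and Il12rb2 were lower at day 3 with IL-1β. Rel, which encodes the NF-κB subunit c-Rel, stood at 3.31 against 10.7 FPKM (-1.44). The activation-induced nuclear receptor Nr4a3 stood at 6.12 against 19.4 FPKM (-1.52). Il12rb2, a chain of the interleukin 12 receptor, stood at 9.71 against 24.9 FPKM (-1.28). The largest drops among counted genes above 0 in both libraries were in Gprin3 (-2.37), Mob1a (-2.33) and Aig1 (-2.25).

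Other helper T cell genes did not meet the rule at day 3. Il10 stood at 13.7 against 7.51 FPKM, Il21 at 3.59 against 2.12 FPKM and Ifng at 78.3 against 44.0 FPKM. The transcription factor genes were close, with Irf1 at 30.0 against 29.7 FPKM, Gata3 at 204 against 194 FPKM and Foxp3 at 7.61 against 7.55 FPKM. Irf4 stood at 94.7 against 118 FPKM and Batf at 170 against 122 FPKM. Of 34 measured interferon response genes 1 was higher, Gbp2 at 16.9 against 7.11 FPKM (1.15), and the list's median was 0.21, above 98.6% of random lists. The markers of myeloid cells (0.39) and of NK and CD8 cells (0.53) and the transcripts without a poly(A) tail (0.43) also lay above the middle 95% of random lists. NF-κB targets had 0 of 28 higher and 1 lower (Rel), with 14 ratios above and 14 below 0 on the log2 scale. None of the 11 measured Th17 markers met the rule, and their median was 0.43, above 99.4% of random lists. Cell cycle genes had 0 of 36 counted either way and a median of -0.17, and cholesterol biosynthesis genes 0 of 20 and -0.26. Both medians lay below the middle 95% of random lists, as did those of the naive and memory genes (-0.27) and T cell identity genes (-0.09).

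In all, 104 of 7962 compared genes were higher and 171 were lower at day 3. The ratio at day 3 fell with transcript length, with a Spearman correlation across 6945 genes of -0.58, where genes are not independent replicates. With genes in 5 bins by length, the median log2 ratio was 0.38 in the shortest bin and -0.41 in the longest. With this trend removed, a check added after seeing the data, 81 genes were higher and 93 lower, Il9 kept a log2 ratio of 2.25, and Mt1, Nupr1, Mcpt8, Gbp2, Rel, Nr4a3 and Il12rb2 still met the rule, while Cxcl3, with a log2 ratio of 1.76 and intervals still apart, missed the 5 FPKM floor at 4.69 FPKM. Of 9 lists outside the middle 95% of random lists, 1 remained outside, the cell cycle genes at -0.11, and 3 others came to lie outside. The interferon response median was then 0.11, above 93.5% of random lists.

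**Figure D1:**
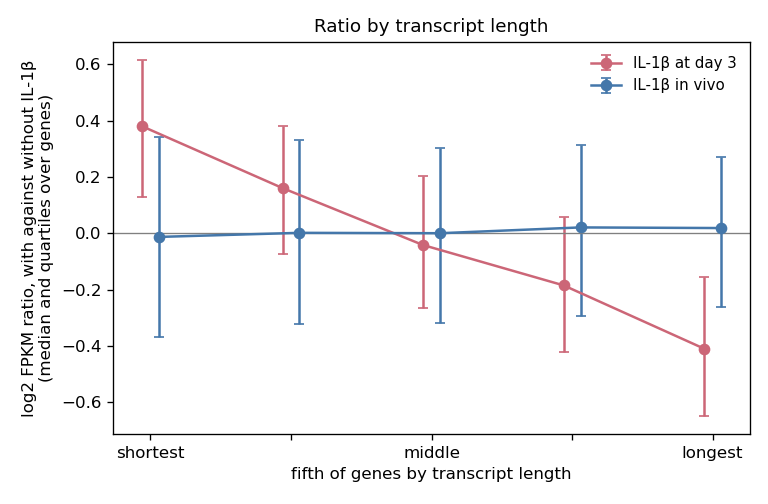
Median log2 FPKM ratio with against without IL-1β in 5 bins of genes ordered by transcript length, at day 3 and in vivo, with bars for the quartiles over genes. At day 3 the medians run from 0.38 in the shortest to -0.41 in the longest bin, and in vivo from -0.01 to 0.02.

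The in vivo comparison asked whether cells differentiated with IL-1β still differ after injection into mice. Many interferon response genes were higher in the library with IL-1β. Of 37 measured members 20 were higher and 0 lower, with a median log2 ratio of 1.19, above all 10000 random lists. Irf1 (chromosome 11, 53583516 to 53591876), a transcription factor induced by interferon, was higher at 84.2 FPKM (72.4 to 95.7) against 31.8 (24.9 to 38.8), a log2 ratio of 1.38. The guanylate-binding protein gene Gbp2 was higher at 87.1 against 8.13 FPKM (3.27), Iigp1 at 22.4 against 2.31 FPKM (2.82) and Irf7 at 31.5 against 5.13 FPKM (2.41).

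Cytokine genes of several helper states were higher in the same library. Ifng (chromosome 10, 117878103 to 117882948) stood at 86.3 FPKM (58.3 to 90.3) against 11.4 (5.76 to 16.7), a log2 ratio of 2.81. Il10 (chromosome 1, 132916422 to 132921547) was higher at 23.1 against 3.24 FPKM (2.51), and Il17a at 15.4 against 1.48 FPKM (2.73). Il5 was higher at 39.0 against 16.6 FPKM (1.19), and Il3 reached 12.4 FPKM against a listed 0. Foxp3, the regulatory T cell transcription factor gene, was higher at 13.3 against 4.44 FPKM (1.39). The Th9 cytokine gene itself did not meet the rule, with Il9 at 49.6 against 59.5 FPKM (-0.26). Il21 (0.719 against 4.40 FPKM), Gata3 (125 against 210 FPKM), Irf4 (85.8 against 71.0 FPKM), Batf (108 against 120 FPKM), Il4 (9.88 against 17.1 FPKM), Sfpi1 (15.0 against 10.7 FPKM) and Il1r1 (3.17 against 0.771 FPKM) did not meet it either.

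Several effector and activation genes were also higher. Early activation genes had 13 of 28 members higher and a median of 0.99, among them Fosb at 61.8 against 9.61 FPKM (2.57), Cd69 at 53.3 against 9.01 FPKM (2.44) and Fos at 142 against 30.3 FPKM (2.19). Cytotoxic effector genes had 5 of 16 higher and a median of 0.88, with granzyme A (Gzma) at 90.5 against 7.54 FPKM (3.42) and granzyme B (Gzmb) at 771 against 335 FPKM (1.20). Th1 markers had 4 of 17 higher (median 0.90) and Th17 markers 4 of 14 (median 1.10). NF-κB targets had 4 of 29 higher, with a median of 0.40, including Tnfaip3, a feedback inhibitor of NF-κB, at 88.7 against 21.6 FPKM (1.99) and Csf2 at 26.8 against 6.08 FPKM (1.97). Th9 genes had 4 of 27 higher (Il10, Etv5, Smad7 and Ccl22) and a median of 0.27, inside the middle 95% of random lists. The Th2 list had 4 of 17 higher, Il3, Maf, Il5 and Il10, and a median of -0.01.

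Genes of proliferation and sterol synthesis were lower in the library with IL-1β. Of 36 cell cycle genes 21 were lower and 0 higher, with a median of -1.11, below all random lists. The kinesin gene Kif11 stood at 17.9 against 62.6 FPKM (-1.75) and the proliferation marker Mki67 at 25.3 against 73.7 FPKM (-1.50). Of 20 cholesterol biosynthesis genes 16 were lower, with a median of -1.43. Hmgcs1, an enzyme gene of the mevalonate pathway, stood at 19.9 FPKM (15.6 to 24.0) against 112 (98.3 to 123), a log2 ratio of -2.44, and Fdps at 8.15 against 49.7 FPKM (-2.47). None of 14 T cell identity genes met the rule, with a median of -0.16 and a range from -0.47 for Cd2 to 0.68 for Lat.

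Transcripts of other cell types were present in both in vivo libraries and several were higher in the one with IL-1β. The values do not show which cells carried the interferon response and early activation RNA. Markers of stroma and epithelium had 8 of 12 members higher and a median of 1.62, and myeloid markers 4 of 20 and 0.89. Sftpc, the surfactant gene of alveolar epithelium, stood at 10010.5 against 3512 FPKM (1.51), the lysozyme gene Lyz2 at 1614 against 521 FPKM (1.63), and the collagen gene Col1a1 at 12.0 against 0.778 FPKM (2.87). Gpx3, a secreted glutathione peroxidase, had the largest ratio among counted genes above 0 in both libraries, 171 against 7.42 FPKM (4.36). B and plasma cell markers had 1 of 10 higher (Sdc1) and 1 lower (Cd79b), with a median of -0.39.

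In all, 540 of 8639 compared genes were higher and 301 were lower in vivo. Among genes with at least 5 FPKM in both day 3 libraries, a restriction added after seeing the data, 139 genes were higher. Within that restriction 10 of 22 interferon response genes were higher with a median of 1.06, and 9 of 24 early activation genes with a median of 0.95. The median of the Th17 markers was 1.06 and that of the cytotoxic effector genes 0.81. The Th1 median went from 0.90 to 0.34, with 3 of 10 higher, and that of homing receptors and integrins from 0.63 to 0.32. The Th2 median went from -0.01 to -0.38 and the regulatory T cell median from -0.23 to -0.44, both then below the middle 95% of random lists.

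**Figure D2:**
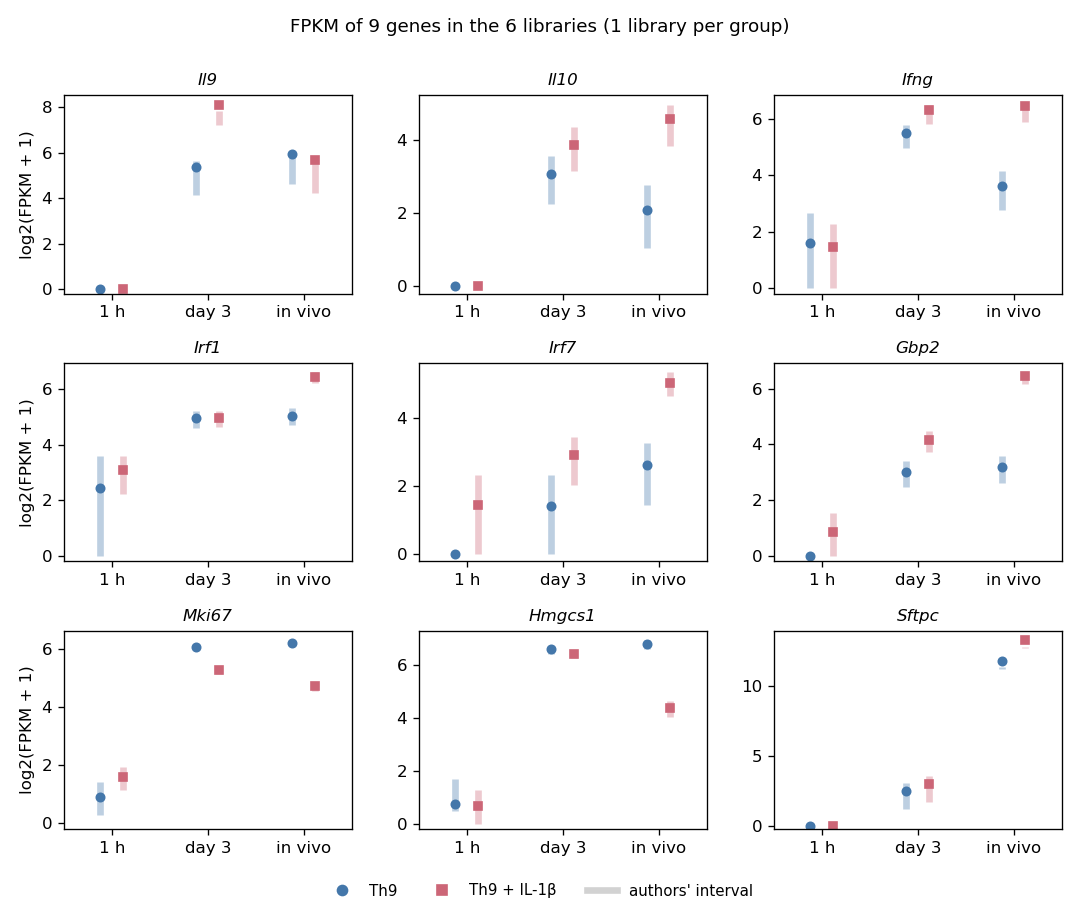
FPKM on a log2 scale, with 1 added, of 9 genes in the 6 libraries; each point is 1 library and each bar the authors' interval. Il9 separates at day 3 (274 against 39.8 FPKM), and Il10, Ifng, Irf1, Irf7 and Gbp2 separate in vivo.

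**Figure D3:**
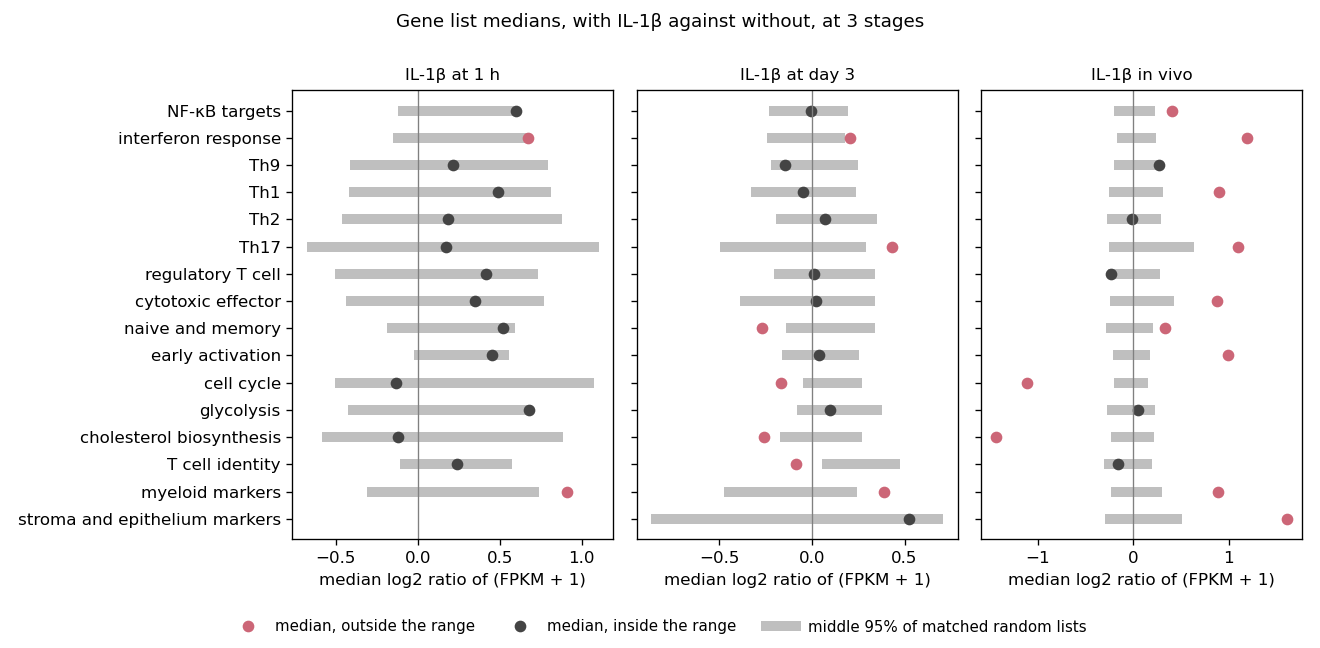
Median log2 ratio of gene lists with against without IL-1β at the 3 stages, with grey bars for the middle 95% of random lists matched on expression. In vivo the interferon response median is 1.19 and the cell cycle and cholesterol biosynthesis medians are -1.11 and -1.43.

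Whether IL-1β acted on the same genes at different stages was examined next. Gbp2, Mt1, Mcpt8, Cxcl3, the heme oxygenase gene Hmox1, Bysl, Exosc9, Tbc1d17 and the unnamed models 2010002N04Rik and 4933439C10Rik were higher both at day 3 and in vivo. These 10 genes compare with 1.74 for independent lists. Lower at both stages were 14 genes, against 5.87 for independent lists, among them the cell cycle kinase gene Cdk6, Hmga1, Fancd2 and Bzrap1. Bysl, Exosc9, Tbc1d17 and 4933439C10Rik were listed at 0 without IL-1β at both stages. With genes listed at 0 in any of the 4 libraries left out, a check added after seeing the data, 5 genes were higher at both stages against 1.32 for independent lists, and 11 lower against 5.13. Hmox1 stood at 22.0 against 10.0 FPKM at day 3 and at 35.7 against 12.4 FPKM in vivo. Cd69, Cxcr4, Tagap and Rn4.5s were higher both at 1 h and in vivo, 4 genes against 4.70 for independent lists. Rpl9 and Tbca were higher at 1 h and at day 3, 2 genes against 1.18. Across genes, the Pearson correlation of the log2 ratios was 0.09 between day 3 and in vivo (7700 genes). Between 1 h and day 3 it was -0.02 (863 genes), with a Spearman value of -0.12, and -0.16 over the 796 genes above 0. Between 1 h and in vivo it was -0.06 (879 genes), with a Spearman value of 0.03, and 0.04 over the 807 genes above 0. These pairs of comparisons share no library.

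A difference common to the 3 stages was tested with limma, with stage as a covariate, which leaves 2 residual degrees of freedom. It called 0 of 8946 genes, with 320 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.937. Without the 1 h stage, an alternative fixed in advance, with 1 residual degree of freedom, limma called 34 genes, 27 higher and 7 lower. Of these, 7 were above 0 in all 4 libraries: Cxcl3, Mt1, the second metallothionein gene Mt2, Irf7, Bzrap1 and the histone genes Hist1h4h and Hist1h2bj. Mt2 stood at 13.6 against 4.69 FPKM at day 3 and 42.0 against 6.44 FPKM in vivo. Leaving out day 3 or the in vivo stage gave 0 calls, with smallest adjusted p values of 0.0943 and 0.121, at 357 and 340 genes with an unadjusted p under 0.05.

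The comparison of day 3 with 1 h followed each arm through culture, and time cannot be told apart from the change in RNA selection. Most compared genes stood higher in FPKM at day 3. Without IL-1β, the receptor genes Il2ra (502 FPKM) and Tnfrsf18 (549 FPKM) and the transcription factor gene Gata3 (194 FPKM) were listed at 0 at 1 h. The lectin gene Lgals1 rose from 3.30 to 949 FPKM and the glycolysis gene Ldha from 8.72 to 795 FPKM. With IL-1β, Il9 reached 274 FPKM from a listed 0, and granzyme B (Gzmb) rose from 1.45 to 443 FPKM. The structured RNAs went the other way, with Rn45s at 145 FPKM at day 3 against 58843 at 1 h without IL-1β and 144 against 56674 with it. Fosb was lower at day 3, at 0.618 against 7.68 FPKM without IL-1β and 0.170 against 13.2 FPKM with it. With IL-1β, Nr4a3 (6.12 against 36.0 FPKM) and Cd69 (17.5 against 51.2 FPKM) were lower as well.

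By FPKM as deposited, 7357 genes were higher and 23 lower at day 3 without IL-1β, and 7057 and 44 with IL-1β. The median ratios of genes at 5 FPKM or more in both libraries were 3.46 and 3.32. With these shifts scaled away, 2042 genes were higher and 217 lower without IL-1β, and 2053 and 583 with IL-1β, so that the share of higher genes among those counted went from 99.4% to 77.9% in the second case. Equal upper quartiles gave 1935 higher and 628 lower with IL-1β, a share of 75.5%. After scaling to equal median ratios, with the pseudocount added afterwards, the cell cycle median was 3.34 without IL-1β and 2.90 with it. As deposited it was 5.31 and 5.06. The scaled glycolysis median was 2.98 and 2.73, and the scaled cholesterol biosynthesis median 2.90 and 2.23. Genes near 0 at 1 h lose only part of the shift in this way, so these medians depend on the pseudocount. Only 11 of 36 cell cycle genes reached 1 FPKM in either 1 h library. By FPKM as deposited, all 36 measured cell cycle, 17 glycolysis and 20 cholesterol biosynthesis genes were higher in both arms. After the same scaling to equal median ratios, early activation genes had medians of -1.34 and -1.27, and the transcripts without a poly(A) tail -3.28 and -3.04.

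The comparison of the in vivo stage with day 3 asked what changed in each arm after injection. In the arm without IL-1β, Ifng was lower in vivo at 11.4 against 44.0 FPKM (-1.86) and Il17a at 1.48 against 8.55 FPKM (-1.94). The immediate early genes Fosb (9.61 against 0.618 FPKM), Jun (29.9 against 5.55 FPKM), Fos (30.3 against 5.84 FPKM) and Dusp1 (43.5 against 13.6 FPKM) were higher, 4 of 27 measured early activation genes. Sfpi1, which encodes the transcription factor PU.1, was higher at 10.7 against 0.488 FPKM (2.98). Transcripts of other cell types rose in the same library, so these values do not show which cells carried the Sfpi1 and immediate early RNA. The largest rises among genes above 0 in both libraries were in Sftpc (3512 against 4.60 FPKM) and the secretoglobin gene Scgb1a1 (2736 against 6.25 FPKM), and Lyz2 reached 521 FPKM from a listed 0. Myeloid markers had 11 of 18 members higher, including S100a8 (107 against 2.91 FPKM), and stroma and epithelium markers 3 of 9. None of 17 glycolysis genes met the rule, and their median of -0.42 lay below all random lists. Il9 stood at 59.5 against 39.8 FPKM and did not meet the rule.

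In the arm with IL-1β, Il9 was lower in vivo at 49.6 FPKM (17.7 to 48.0) against 274 at day 3 (149 to 227), a log2 ratio of -2.44. Interferon response genes had 18 of 37 members higher and a median of 1.02, with Irf1 at 84.2 against 30.0 FPKM (1.46) and Irf7 at 31.5 against 6.45 FPKM (2.13). Early activation genes had 13 of 28 higher and a median of 1.00, with Fosb at 61.8 against 0.170 FPKM (5.75) and Jun at 134 against 4.06 FPKM (4.74). Cell cycle genes had 15 of 36 lower and a median of -0.91, and cholesterol biosynthesis genes 10 of 20 lower and a median of -1.00. Ifng (86.3 against 78.3 FPKM) and Il17a (15.4 against 11.9 FPKM) did not meet the rule. Myeloid markers had 15 of 20 higher, stroma and epithelium markers 10 of 12, and T cell identity genes 0 of 14 either way.

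In all, 173 of 8126 genes were higher and 55 lower in vivo without IL-1β, and 1033 of 8572 higher and 504 lower with it. With IL-1β, equal upper quartiles (a shift of 0.21) gave 1452 higher and 272 lower, a share of 84.2% against 67.2%, and removing the transcript length trend (Spearman 0.43) gave 959 and 324. Without IL-1β, equal upper quartiles shifted the ratios by 0.15 and gave 209 higher and 39 lower. Among genes with at least 5 FPKM in both day 3 libraries, the higher counts were 30 without IL-1β and 306 with it.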

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

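The test of overlapping loci in this part was written before its result was seen; the removal of the length trend was chosen after it was seen. None of the differences between groups given here was tested, since each rests on 1 library per group.

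Some genes were counted in opposite directions by the same comparison at different stages or in different arms. IL-1β gave 8 such genes between day 3 and in vivo: Rad9, Exosc6, Oip5, Yipf2, Gm7367, 1110054M08Rik, Dnajb13 and Lgals7. Following each arm from day 3 to in vivo, which uses the same 4 libraries, gave 7 of these genes, all but Lgals7. Among 7700 genes compared for IL-1β at both stages, 76 were higher and 157 lower at day 3, and 176 and 288 in vivo. Whether 8 opposite genes exceed what independent lists would give was not tested. Rad9 (mm9 chromosome 19, 4195198 to 4201603), a DNA damage checkpoint gene, stood at 36.7 FPKM at day 3 without IL-1β and 26.0 FPKM in vivo with IL-1β. It was listed at 0 in the other 2 libraries of these stages. From 1 h to day 3 there was 1 such gene, Abhd2, which went from 2.33 to 9.20 FPKM without IL-1β and from 6.0 to 1.57 FPKM with it.

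Of the 8 genes, 6 were listed at 0 in at least 1 of the 4 libraries and 6 had a locus that overlaps another gene's, as Rad9 overlaps Ppp1ca and Exosc6 overlaps Aars. Among all genes counted at day 3 or in vivo that were listed at 0 in 1 library of the pair and at 10 FPKM or more in the other, 32 of 40 overlapped another locus. That is 80% (95% Wilson interval 65.2% to 89.5%), against 16.2% (15.3% to 17.1%) of 6741 other genes at 10 FPKM or more. Values of 0 that come and go between libraries may therefore arise from fragments shared with an overlapping gene model. A change in the expression of the single genes stays open, as untested.

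The naive and memory genes had a median log2 ratio of -0.27 with IL-1β at day 3 and 0.33 in vivo, and the day 3 value was -0.03 with the length trend removed. From day 3 to in vivo, the cholesterol biosynthesis genes had a median of 0.11 without IL-1β and -1.00 with it. Among the entries without an OK status, which no comparison used, 29 had an interval above 0 in at least 1 library, such as Rplp2-ps1 at 809 and 1244 FPKM and Gm5506 at 338 and 433 FPKM at day 3 without and with IL-1β.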

How the results depend on the processing

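Leaving out genes listed at 0, keeping genes at 5 FPKM in both day 3 libraries, removing the length trend, and the splits of the libraries were chosen after the results were seen; the other alternatives were fixed before. Over 178 alternatives of the counts and correlations, 116 stayed close to the value reported, 59 moved, 1 became a call and 2 ended one. Of 912 alternatives of list medians, 726 stayed close, 159 moved and 27 reversed. The 27 are not all of the sign changes, since some medians counted as moved also changed sign. All 225 ratios of named genes kept their sign in all settings run on them. The counts that moved by over 1.5 times follow, as higher and lower, with IL-1β at 1 h, day 3 and in vivo, then day 3 against 1 h and in vivo against day 3 without and with IL-1β.

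A pseudocount of 5 gave 49 higher at 1 h, 40 lower at day 3, 328 and 165 in vivo, 30 lower in vivo against day 3 without IL-1β, and 622 higher with it. No filter on low values gave 388 and 9 at 1 h, 263 lower at day 3, 834 higher in vivo, and in vivo against day 3 391 and 88 without and 1722 higher with IL-1β. A minimum of 20 FPKM gave 10 and 0 at 1 h, 53 and 34 at day 3, and 202 and 161 in vivo. Over time it gave 3499 and 3431 higher at day 3, and in vivo 58 and 17 without and 316 higher with IL-1β. A 3-fold minimum gave 45 and 37 at day 3, 295 and 72 in vivo, 22 lower over time without and 575 and 120 with IL-1β. No use of the intervals gave 180 and 91 at 1 h, 199 higher at day 3, 54 and 71 lower at day 3 against 1 h, and 100 lower in vivo without IL-1β. Those filters and minimums move counts by construction, as fewer or more genes can pass.

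Equal median ratios gave 47 higher at 1 h and, at day 3 against 1 h, 2042 and 217 without and 2053 and 583 with IL-1β. Equal upper quartiles gave 113 higher at 1 h, 2385 and 165, and 1935 and 628, and 272 lower in vivo with IL-1β. Leaving out genes listed at 0 gave 37 and 0 at 1 h, 4151 and 11 at day 3 against 1 h without and 23 lower with IL-1β, and 99 higher in vivo without IL-1β; the correlation between 1 h and day 3 was -0.16. Keeping genes at 5 FPKM in both day 3 libraries gave 139 higher in vivo with against without IL-1β, and 30 and 306 over time. Removing the length trend gave 93 lower at day 3 and 324 lower in vivo against day 3 with IL-1β. At 1 h and at day 3 against 1 h, removing the fitted curve was not tallied among the alternatives, but counts moved there too. The curve holds the overall shift between the 2 libraries as well as any slope with length. Its removal gave 42 higher at 1 h, where ratio and length had a Spearman correlation of 0.05 and the shift was 0.21. At day 3 against 1 h, with shifts of 3.46 and 3.32, it gave 987 and 93 without and 948 and 166 with IL-1β. These counts therefore do not measure an effect of length alone. The correlation of 1 h with in vivo was -0.24 at a minimum of 20 FPKM, where the cause was not tested.

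The reversed medians all but 1 concern day 3 against 1 h, where both scalings remove a shift of over 3 log2 units by construction. Without IL-1β, equal median ratios and equal upper quartiles gave -0.55 and -0.33 for follicular helper, -1.00 and -0.79 for cytotoxic, -1.34 and -1.08 for early activation, and -1.66 and -1.46 for NK and CD8 genes. Equal median ratios alone gave -0.034 for NF-κB targets and -0.076 for naive and memory genes. With IL-1β the values were -0.35 and -0.42 for NF-κB targets, -0.35 and -0.40 for interferon response, -0.99 and -1.03 for cytotoxic, -0.73 and -0.81 for naive and memory, -1.27 and -1.35 for early activation, -0.67 and -0.74 for homing, -3.07 and -3.14 for myeloid, and -1.10 and -1.16 for NK and CD8 genes. The T cell identity median in vivo against day 3 with IL-1β was 0.13 with equal upper quartiles, which add 0.21. Sign changes among the medians that moved include 2 at day 3 against 1 h with equal median ratios. Inhibitory receptors went from 2.33 to -0.089 without IL-1β, and Th1 markers from 2.66 to -0.049 with it.

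limma called 34 genes without the 1 h stage and 0 in its other settings, with 10 to 405 genes at an unadjusted p under 0.05, and 27 of the 34 were listed at 0 in a library; the cause was not tested. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05; the real one gave 0 genes and the highest other 16. That count came with 1367 genes at an unadjusted p under 0.05 against 320. That split parts the 1 h pair alone and keeps the day 3 and in vivo pairs together. With stage in the fit it measures the 1 h difference, so it is no like comparison for the real split. The other splits that part the pair of every stage, as the real one does, gave 0 calls. They had 175, 243 and 282 genes at an unadjusted p under 0.05, against 320 for the real one. By replicate number, no paired analysis was possible because each group has 1 library; stage is the block of the limma fit. Depth is unknown; the intervals were widest at 1 h, where the size rule counted 20 of 100 genes lowered 3-fold in simulated data.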

Other observations

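The tests in this part were all chosen after the results were seen.

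Several gene groups in vivo have not been described yet, each as cells given IL-1β against cells without it. The transcription factor genes Klf2 (181 against 68.0 FPKM) and Klf3 (26.9 against 8.35 FPKM) were higher, 2 of 16 naive and memory genes. The follicular helper list had 2 of 11 members higher, the checkpoint receptor gene Pdcd1 (16.5 against 4.91 FPKM) and the transcription factor gene Bcl6 (8.03 against 2.28 FPKM), with a median of 0.05. Inhibitory receptors had 4 of 12 higher and a median of 0.12, and regulatory T cell markers 4 of 17 higher and a median of -0.23. In IL-1 receptor signalling, 1 of 16 was higher, the adaptor gene Myd88 at 36.4 against 17.4 FPKM. Of 17 glycolysis genes 1 was lower, Aldoc at 6.99 against 31.2 FPKM. Homing receptors and integrins had 2 of 17 higher (median 0.63), erythroid and platelet markers 2 of 7 (median 1.13), NK and CD8 cell markers 1 of 6 (median 0.48), and the core genes 6 of 14 (median 0.82). Of 31 transcripts without a poly(A) tail 1 was lower.

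Transcripts of other cell classes differed between the in vivo libraries by unequal amounts, by a marker list written after surfactant and secretoglobin transcripts were seen. Of 17 airway and alveolar epithelium genes 13 were higher with IL-1β, with a median of 1.51 and a sum of 18838 against 7256 FPKM. At day 3 the same genes summed to 21.7 and 20.9 FPKM. Stromal genes were higher for 11 of 12 members with a median of 2.94, such as the elastic fibre gene Mfap4 at 125 against 9.23 FPKM and Mgp at 266 against 36.0 FPKM. Endothelial genes were higher for 5 of 7 with a median of 1.32. Of 6 neutrophil genes 1 was higher, with a median of 0.58. Among them S100a8 stood at 107 against 107 FPKM, S100a9 at 116 against 117 FPKM and Lcn2 at 71.8 against 30.2 FPKM.

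The in vivo difference, with interferon response genes higher and cell cycle and cholesterol biosynthesis genes lower, could partly come from RNA of other cells. Epithelial RNA was present in vivo despite the sort for CD45.2. Sftpc stood there at 10010.5 FPKM with and 3512 FPKM without IL-1β, against 7.04 and 4.60 FPKM at day 3. Against dilution by RNA of cells that are not T cells, the T cell identity genes had a median of -0.16 and none below -0.47, while the cell cycle and cholesterol medians were -1.11 and -1.43. For the interferon response, levels extrapolated from the gain of epithelial genes (a factor of 2.85) fell short of the observed ones by a median of 1.24 on the log2 scale (quartiles 0.30 to 1.71). With the factor of 8.87 from stromal genes the median was 0.89 with quartiles from -0.67 to 2.60. RNA of other cells and a difference in the T cells therefore cannot be told apart for the interferon response genes. Early activation genes lay above the extrapolated levels by a median of 1.12 (quartiles 0.44 to 2.08) with the epithelial factor. With the stromal factor their median was 1.51 (-0.30 to 4.85), so the 2 explanations cannot be told apart for this list either. Cell cycle genes lay at a median of -0.50 (quartiles -1.18 to 0.007) relative to the levels extrapolated with the epithelial factor. With the stromal factor the median was 1.07 (-1.39 to 4.24), so the extrapolation does not separate the 2 explanations for them either. Cholesterol biosynthesis genes lay below the extrapolated levels with both factors, at -1.47 (-1.79 to -0.87) and -2.01 (-2.62 to -0.17). IL-1β itself stays open as the source, untested for want of replicates.

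At day 3, Il9 was higher and more genes were lower than higher with IL-1β, and the ratios ran with transcript length. With the length trend removed the lower count went from 171 to 93 beside 81 higher. The excess of lower genes may therefore come from this trend between the 2 day 3 libraries. Ratio and length had a Spearman correlation of -0.58 here and 0.43 for in vivo against day 3 with IL-1β. It was 0.06 for in vivo against day 3 without IL-1β and 0.02 for IL-1β in vivo. The trend thus lies with the day 3 library with IL-1β, which the fall of Il9 in vivo in that arm also uses. The trend as the whole cause of the Il9 difference is argued against by its log2 ratio of 2.25 after removal, with intervals that stayed apart. A higher Il9 level in cells given IL-1β may be biological and stays a hypothesis, found and tested in the same 2 libraries.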
